A study of Mus musculus with 36 samples.

How the data were processed

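RNA was measured by sequencing in 12 mouse libraries from cells lacking MLL3 (the gene Kmt2c) that either kept the conditional MLL4 allele (Kmt2d; MLL3-/-;MLL4flox/flox, called f/f here) or had lost it (MLL3-/-;MLL4-/-, called DKO here). The cells were embryonic stem cells (ESC), embryoid bodies made from them by 4 days of suspension culture without LIF, immortalised embryonic fibroblasts (MEF), and those fibroblasts 20 days after lentiviral delivery of Oct4, Sox, Klf4 and c-Myc (the labels do not say which Sox gene, and Sox2 was taken as the factor). Per the labels, ESC were kept on irradiated fibroblast feeders with LIF, and poly(A) RNA was taken with Dynabeads and made into Illumina TruSeq libraries. The series holds 36 samples, and the 24 chromatin and input samples were not analysed here.

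Each ESC and embryoid body group had 2 libraries, 1 in each of 2 batches. Replicate 1 of these groups was deposited as a read count and an RPKM value per RefSeq transcript, per the file headers. Replicate 2, whose titles carry their own suffix, and the 4 fibroblast and day-20 libraries were deposited as 1 FPKM value per Entrez gene, per the file headers. The submitters' processing notes name the mouse build mm9, bedtools 2.16 and SICER 1.1 for the first batch, and CASAVA 1.8.2 and SICER for the second. The aligner, the annotation release, the strand setting and the treatment of reads shared by overlapping transcripts are not given in the sources used here, and antisense, overlapping and near-identical genes are uncertain for that reason. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

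Transcripts were joined to genes by accession in a gene table for GRCm38.p6, of which only names were used. Of 29082 transcripts, 28436 matched, giving 22463 genes, of which 22456 were also in the FPKM files. For the 3760 genes with more than 1 transcript, the transcript with the most reads stood for the gene. Of 24284 genes in the FPKM files, 24203 matched the table. Depth behind the deposited RPKM values was recovered from counts, RPKM and transcript lengths. Depth behind the deposited FPKM values was recovered from the steps of low genes with 1 transcript of known length. Of those genes, 90.7% to 92.3% per library were whole multiples of 1 read within a tolerance of 0.02 reads. With that depth, FPKM values of 24283 genes gave whole reads after a search over gene lengths, which is no check of the depth. The depth behind the values lay between 11366199 reads (replicate 2 of the f/f bodies) and 38264157 reads (DKO fibroblasts).

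The batches were counted differently as well as scaled differently. Rpl10 stood at 6.28 RPKM in replicate 1 of f/f ESC and at 1200.1 FPKM in replicate 2, so levels were compared only within a batch. Libraries of the same batch deviated together from their group means, with correlations across genes of 0.864 to 0.954 between groups, and the batch entered the model as a block. Each difference between groups of ESC or bodies is therefore a mean over 2 batches, with 1 library per group in each.

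The main test was limma 3.58.1 (R 4.3.3; moderated by empirical Bayes with a mean-variance trend, two-sided) on log2(value + 1), with the 4 stage and genotype groups and the batch as terms, over the 8 ESC and embryoid body libraries. Fold changes are on this scale, which understates changes of low genes. Genes with a mean of at least 1 over the 8 libraries were tested (12466 genes), leaving 3 residual degrees of freedom beside 3.27 prior ones, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. The 5 contrasts were DKO against f/f in ESC and in bodies, bodies against ESC in each genotype, and the difference of the genotype effects (interaction). A rule applied to all contrasts named the targeted genes, then the 10 largest increases and the 10 largest decreases past the threshold with the same sign in both batches, and 4 members of each gene list. Genes without a gene symbol word (Gm, Rik, microRNA and similar names) were counted and not named. These choices, the gene lists and most alternatives were made before the data were examined.

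29 gene lists (467 entries, 459 of them matched) covered core, naive and primed pluripotency, primitive streak, definitive endoderm, mesoderm, blood and endothelium, neuroectoderm, extraembryonic endoderm, trophoblast, germline, 2-cell-like cells, fibroblasts and feeders, epithelium, mesenchymal transition, adipogenesis, Hox genes, cell cycle, p53 and arrest, the KMT2 complexes, interferon, immediate early stress, hypoxia and glycolysis, imprinted genes, Wnt, BMP and Nodal targets, ribosomal proteins and housekeeping genes. 28 lists had at least 5 tested members; the 2-cell-like list had fewer and was not tested. Each list was tested with limma's camera, which compares a list with all other genes, with a preset correlation between genes of 0.01 and again with an estimated one, and with fry, which asks whether the genes of a list move without comparing them with other genes. List p-values were adjusted over the 28 lists of a contrast. Some single genes are not reported here.

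Fibroblast and day-20 groups had 1 library each, so nothing was tested. Genes were taken by size alone, with a difference of at least 2 on the log2(FPKM + 1) scale (4-fold) and at least 5 FPKM in the higher library. A list's median difference was given as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, over genes with a mean of at least 1 FPKM; the percentile describes these libraries only. To ask where day-20 cells lay between cell types, genes at least 8-fold higher in f/f ESC (replicate 2) than in f/f MEF, and the reverse, were chosen without the day-20 libraries, with 95% bootstrap intervals from 1000 draws of genes. To follow genes induced or repressed on differentiation, genes at least 2-fold changed in the f/f cells of one batch were measured in the other.

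Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5, median-of-ratios and quantile scaling, no mean-variance trend, no replicate block, a block for each batch within each stage, and leaving out each library. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on whole reads, a mean over transcripts, and fits without 211 small RNA genes or 174 fibroblast genes. On data simulated from the ESC comparison (12248 genes, DKO against f/f), edgeR's dispersion was 0.0385, and the limma test called 37 of 98 genes changed 2-fold (37.8%), 95 of 99 genes changed 4-fold (96.0%) and 14 unchanged genes. The 14 unchanged genes were a larger share of the calls than the threshold of 0.05 allows on average. In the contrast of bodies the same simulated data gave 10 unchanged genes called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for joins, resampling and plots.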

Results

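Messenger RNA was sequenced in 12 mouse libraries. The 8 groups were f/f and DKO cells at each of 4 stages: ESC and day-4 embryoid bodies with 2 libraries per group, and fibroblasts and day-20 factor-treated cells with 1 library per group. Depth behind the deposited values was 18418131 and 21573244 reads in replicates 1 and 2 of f/f ESC, 19747946 and 21531529 in DKO ESC, 18660221 and 11366199 in f/f bodies, and 23147514 and 13463550 in DKO bodies. It was 28921512 reads in f/f and 38264157 in DKO fibroblasts, and 25014405 in f/f and 23413352 in DKO cells at day 20. In the ESC and body groups, paired values below give replicate 1 (RPKM) and then replicate 2 (FPKM), which were counted differently and are not comparable with each other.

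The targeted genes were read first in every library. Kmt2d (MLL4, Entrez gene 381022), which encodes the histone H3 lysine 4 methyltransferase that the DKO cells lack, stood at 13.5 and 18.7 in f/f ESC and at 8.89 and 10.7 in DKO ESC, a log2 difference of -0.65 ± 0.22 (SE, n = 2 per group; limma, adjusted p = 0.155). In bodies it stood at 16.4 and 15.4 in f/f and at 14.3 and 10.1 in DKO, a log2 difference of -0.37 ± 0.22 (SE, n = 2; limma, adjusted p = 0.388). In fibroblasts Kmt2d was 14.4 FPKM in the f/f library and 23.5 FPKM in the library labelled DKO, and at day 20 it was 12.9 FPKM in f/f and 24.8 FPKM in the library labelled DKO. Kmt2c (MLL3, Entrez gene 231051), deleted in all of these cells, lay at 1.89 and 3.44 in f/f ESC and at 1.8 and 2.82 in DKO ESC, between 2.06 and 3.07 in bodies and between 2.79 and 3.06 FPKM in fibroblast and day-20 libraries. These are whole-transcript values, which do not isolate the deleted part of either gene. The deleted exons are not given in the sources used here, so the Kmt2d value checks neither genotype label, and the fibroblast and day-20 values run against the direction of a loss.

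The first comparison, DKO against f/f ESC, asks what MLL4 loss changes in MLL3-null cells that are kept undifferentiated. The small GTPase gene Mras rose 14.5-fold in DKO ESC, from 4.62 and 1.82 to 64.9 and 49.4 (log2 change 3.86 ± 0.34, SE, n = 2; limma, adjusted p = 0.0116). Dppa3, a maternal and naive-state gene, fell 19.6-fold, from 54.6 and 39.1 to 2.23 and 0.795 (log2 change -4.29 ± 0.27, SE, n = 2; limma, adjusted p = 0.0113). Dnmt3l, the cofactor of the DNA methyltransferases DNMT3A and DNMT3B, fell from 141 and 89.2 to 10.1 and 5.04 (log2 change -3.79 ± 0.39; adjusted p = 0.0116). The interferon-inducible membrane gene Ifitm1 fell from 159 and 113 to 9.59 and 6.41 (log2 change -3.93 ± 0.21; adjusted p = 0.0113). The other large decreases, on the log2 scale, were in the transcription factor Tfap2c (-3.59 ± 0.31), the ectoenzyme Enpp3 (-3.55 ± 0.39) and the epithelial GTPase Rab25 (-3.54 ± 0.39). They went on with the septin Septin1 (-3.37 ± 0.62), the Oct4 target Fbxo15 (-3.31 ± 0.36), the ubiquitin ligase adaptor Klhl13 (-3.21 ± 0.49) and the keratin Krt42 (-2.90 ± 0.42). The other large increases were in the adhesion gene Igsf21 (3.29 ± 0.59), the meiotic gene Hormad2 (2.89 ± 0.25), the protease inhibitor A2m (2.79 ± 0.36) and the amino acid transporter Slc38a5 (2.70 ± 0.46). Smaller increases followed in Chst5 (2.48 ± 0.33), Catsperz (2.43 ± 0.22), Tesc (2.31 ± 0.30), the cell cycle inhibitor Cdkn1c (2.01 ± 0.31) and Zbtb7c (2.01 ± 0.26).

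The pluripotency genes of ESC did not move together. Of 17 naive genes, 2 fell (Dppa3 and Fbxo15; 4 fell when adjusted over the list alone) and 15 were not called, with a list mean of -0.60 and a median of 0.11 (camera, adjusted p = 0.325). This result depends on 1 library, since without replicate 2 of DKO ESC the mean was -1.16 and the list passed (adjusted p = 0.01). Klf2 differed by -2.27 ± 0.52 (adjusted p = 0.0693), while Klf4 stood at 88.6 and 88.8 in f/f and at 134 and 228 in DKO. Pou5f1, the gene of Oct4, stood at 409.6 and 650.4 in f/f and at 338 and 515 in DKO. Of 15 core pluripotency genes, L1td1 (-1.06 ± 0.20) and Sall4 (-0.73 ± 0.14) fell, 13 were not called, and 3 fell and 1 rose when adjusted over the list alone. Of 12 primed genes, Sox3 rose (1.52 ± 0.28) and Zic5 fell (-0.94), with 2 up and 3 down when adjusted over the list alone; Dnmt3b differed by -2.31 ± 0.71 (adjusted p = 0.132).

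Epithelial genes were lower in DKO ESC: of 17, 4 fell and 13 were not called (9 fell when adjusted over the list alone). They were Rab25, the splicing regulator Esrp1 (-2.40 ± 0.17), Grhl2 (-1.71 ± 0.29) and the E-cadherin gene Cdh1 (-1.46 ± 0.19), and the list passed camera (adjusted p = 0.00027, but adjusted p = 0.773 with an estimated correlation). Hox genes were higher: of 7 tested out of 39 listed, Hoxb13 rose (1.67 ± 0.26) and 6 rose when adjusted over the list alone. Hoxa10 stood at 2.30 ± 0.57 (adjusted p = 0.0817), and the list passed camera (adjusted p = 0.00017, but adjusted p = 0.713 with an estimated correlation). Of 14 immediate early genes, Atf3 rose (2.00 ± 0.18) both over all genes and over the list alone, and the list passed camera upward (adjusted p = 0.0036, but adjusted p = 0.713 with an estimated correlation). None of 20 ribosomal protein genes was called, and that list passed camera downward (mean -0.30, adjusted p = 0.00011; after quantile scaling the mean was -0.07 and the list did not pass). With an estimated correlation between genes none of these 4 lists passed (camera, adjusted p = 0.713 for the smallest), and none of the 4 passed fry, which compares no list with other genes (adjusted p = 0.120 for the smallest).

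Single genes changed in ESC in lists that did not pass camera. The maternally expressed noncoding genes of the Dlk1-Dio3 region fell, Mirg by 2.32, Rian by 2.10 and Meg3 by 1.70 on the log2 scale; 3 of 15 imprinted genes fell and 3 rose, with 3 and 5 over the list alone. Of 5 blood and endothelial genes Gata2 (1.75 ± 0.33) and Esam rose, and 3 rose over the list alone; the list passed fry (adjusted p = 0.0405). Trophoblast genes gave 2 decreases of 8 (Tfap2c and Wnt7b, -1.96), definitive endoderm 1 of 7 (Prdm1, -1.51 ± 0.20; 2 over the list alone), and extraembryonic endoderm 1 increase of 10 (Sox7, 1.36; 2 up and 1 down over the list alone). Hypoxia genes gave 1 increase (Slc2a1, 0.93) and 2 decreases (Bnip3, -1.08; Pgk1, -0.73) of 16 (2 up and 4 down over the list alone). Germline genes gave 1 decrease of 12 (Prdm1; 4 up and 1 down over the list alone), interferon genes 1 of 7 (Ddx58, -1.47, with the list past fry at adjusted p = 0.0405), and the housekeeping list 1 of 11 (Pgk1; 1 up and 1 down over the list alone). The germline list passed camera upward in some other settings, such as a block for each batch within each stage (adjusted p = 0.0214). Single increases were in mesenchymal transition genes (Twist1, 1.34, of 13), Wnt targets (Cdx1, 1.64, of 10) and BMP targets (Gata2, of 10). No member was called among 11 primitive streak, 8 neuroectoderm, 20 fibroblast, 20 cell cycle, 16 p53, 16 KMT2 complex and 6 adipogenic genes. Adjusted over the list alone, neuroectoderm gave 1 up and 2 down, p53 2 up, and adipogenic genes 1 up and 1 down; lists named in this paragraph whose second count is not given had the same one.

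Over all 12466 genes tested in ESC, 529 passed (limma with Benjamini-Hochberg adjustment), 196 up and 333 down, of which 109 and 202 changed at least 2-fold. The per-gene differences of the batches correlated at 0.763 across genes, which are not independent replicates. The names of the deposited tables have the same number after the genotype for both DKO ESC libraries and for replicate 1 of the DKO bodies. If it names a clone, an effect of that clone cannot be separated from the genotype in these comparisons. The count rests on each ESC library: it was 0 without replicate 1 of f/f ESC, 9 without replicate 1 of DKO ESC, 0 without replicate 2 of f/f ESC and 0 without replicate 2 of DKO ESC. Without replicate 1 or 2 of the f/f bodies, which enter only the shared spread, it was 264 or 275.

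The next comparison, DKO against f/f at day 4, asks what MLL4 loss does to differentiation in embryoid bodies, aggregates that form cells of the germ layers. Tbxt (Brachyury), the transcription factor of the primitive streak, fell 27.6-fold in DKO bodies, from 69.5 and 45.1 to 1.08 and 1.05 (log2 change -4.79 ± 0.57, SE, n = 2; limma, adjusted p = 0.0135). Foxh1, a cofactor of Nodal signalling, fell from 81.2 and 79.9 to 5.69 and 3.91 (log2 change -3.83 ± 0.15; limma, adjusted p = 0.00169), and the streak gene Mixl1 fell from 17.0 and 11.1 to 0.51 and 0.195 (-3.45 ± 0.25; adjusted p = 0.00781). The largest other decreases were in the carbonic anhydrases Car4 (-4.40 ± 0.65) and Car2 (-3.84 ± 0.54), the Wnt target Sp5 (-3.96 ± 0.42) and the noncoding imprinted gene Rian (-3.88 ± 0.41). They went on with the actin binder Tagln (-3.60 ± 0.40), the growth factor Fgf8 (-3.57 ± 0.63) and the adaptor Dok2 (-3.54 ± 0.29). Of the increases, Sohlh2, a transcription factor of early germ cells, rose 12.7-fold (3.66 ± 0.71; adjusted p = 0.0461). Tex13b (3.49 ± 0.60), Hormad2 (3.13 ± 0.25), Gdpd3 (2.91 ± 0.31), A2m (2.84 ± 0.36) and Gpat2 (2.80 ± 0.47) followed, then Dmrt1 (2.76 ± 0.40), Tex19.1 (2.61 ± 0.47), Tcf15 (2.42 ± 0.36) and the metalloprotease Mmp11 (2.38 ± 0.47).

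**Figure D1:**
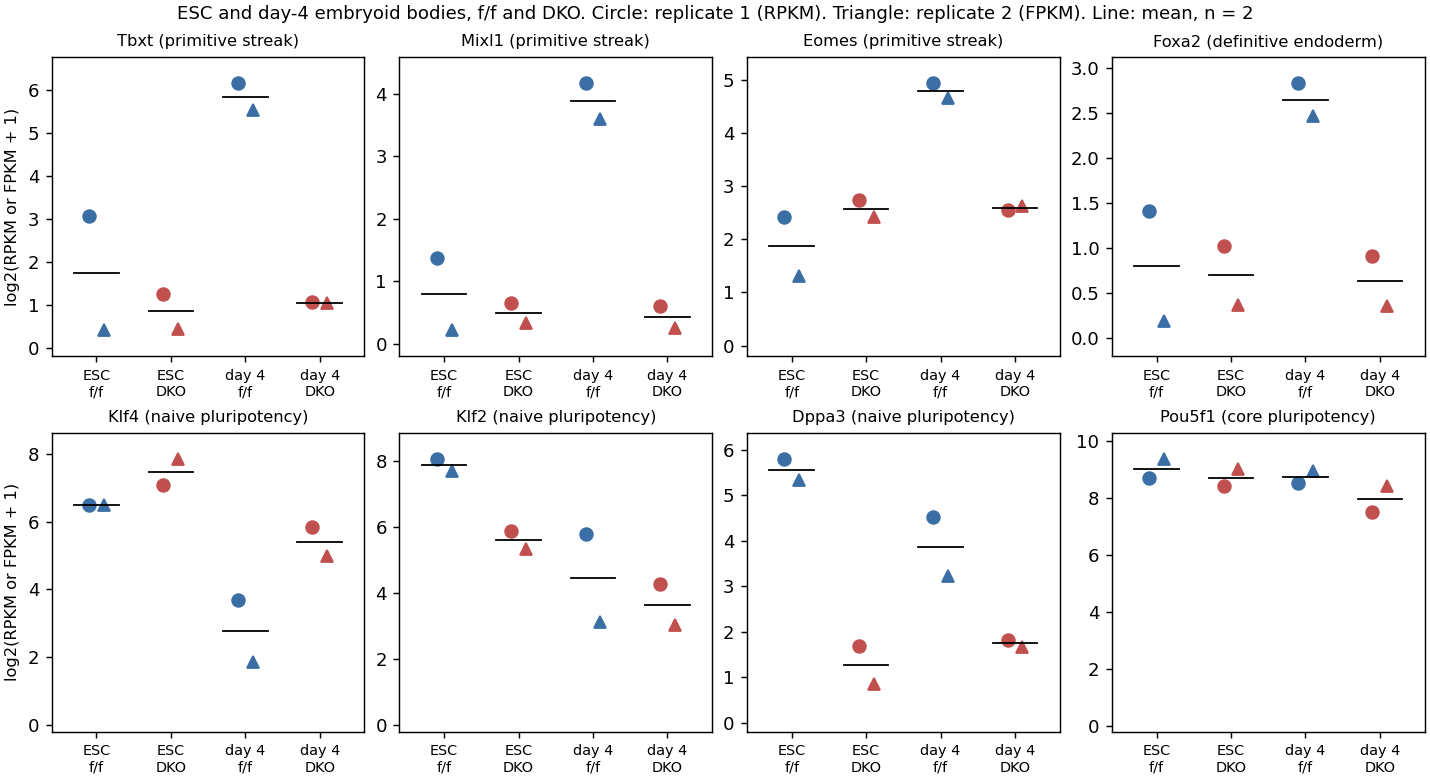
Levels of 8 lineage genes, as log2(RPKM + 1) for replicate 1 (circles) and log2(FPKM + 1) for replicate 2 (triangles), in f/f and DKO ESC and day-4 bodies, with a line at the mean (n = 2). Tbxt stands at 69.5 and 45.1 in f/f bodies and at 1.08 and 1.05 in DKO bodies, while Klf4 stands at 11.8 and 2.60 in f/f bodies and at 56.7 and 30.4 in DKO bodies.

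Primitive streak genes were lower in DKO bodies: 8 of 11 fell and 3 were not called (10 fell when adjusted over the list alone), of which the largest were Tbxt, Fgf8, Mixl1 and Lhx1 (-3.00 ± 0.50). The list mean was -2.51 (camera, adjusted p = 8.9e-10, but adjusted p = 0.362 with an estimated correlation). Of 7 definitive endoderm genes 3 fell and 4 were not called (5 over the list alone), namely Foxa2 (-2.01 ± 0.24), Gata4 (-1.99 ± 0.30) and Gata6 (-1.36 ± 0.22; camera, adjusted p = 0.00015, but adjusted p = 0.290 with an estimated correlation). Of 7 mesoderm genes 2 fell, among them Msx1 (-2.09 ± 0.29; 4 down and 1 up over the list alone; camera, adjusted p = 0.0048, but adjusted p = 0.362 with an estimated correlation). Without replicate 2 of the DKO bodies the mesoderm list did not pass (adjusted p = 0.0634). Hand1, which stood at 1.78 and 62.0 in f/f bodies, differed by -3.01 ± 1.23 (limma, adjusted p = 0.231). Nodal targets gave 2 decreases of 8 (among them Fgf8; 4 over the list alone; camera, adjusted p = 0.00015, but adjusted p = 0.290 with an estimated correlation). Extraembryonic endoderm genes gave 5 of 10 (6 over the list alone), among them the matrix gene Sparc (-2.67 ± 0.26) and the activin antagonist Fst (-1.95 ± 0.37; camera, adjusted p = 0.00028, but adjusted p = 0.407 with an estimated correlation). Trophoblast genes gave 1 of 8 (Wnt7b, -1.26 ± 0.25; 5 over the list alone; camera, adjusted p = 0.00071, but adjusted p = 0.290 with an estimated correlation), with Krt8 at -2.89 (adjusted p = 0.0629) and Krt18 at -2.57 (adjusted p = 0.066).

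Epithelial genes were lower in DKO bodies as in DKO ESC. Of 17, 8 fell and 9 were not called (16 fell when adjusted over the list alone). Among them were the tight junction gene Cldn3 (-3.30 ± 0.40), the desmosome gene Dsp (-3.20 ± 0.44), Rab25 (-3.16 ± 0.39) and the keratin Krt19 (-3.02 ± 0.45), with a list mean of -2.08 (camera, adjusted p = 8.6e-12, but adjusted p = 0.362 with an estimated correlation). Primed epiblast genes gave 2 decreases of 12, both also over the list alone, Sox3 (-2.15 ± 0.28) and Zic2 (-0.76 ± 0.15; camera, adjusted p = 0.004, but adjusted p = 0.588 with an estimated correlation). The primed call rests on 1 library, since without replicate 1 of the DKO bodies the list mean went from -0.84 to -0.13 (adjusted p = 0.849). Dnmt3b was 196 and 282 in f/f but 24.5 and 146 in DKO (-1.95 ± 0.71, adjusted p = 0.19). Immediate early genes gave 2 decreases of 14 (5 over the list alone), Ccn1 (-2.16 ± 0.37) and Atf3 (-1.04 ± 0.18; camera, adjusted p = 0.0033, but adjusted p = 0.413 with an estimated correlation). That list did not pass without replicate 2 of the f/f bodies (adjusted p = 0.103) or of the DKO bodies (adjusted p = 0.0690).

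Naive genes went both ways in DKO bodies. Of 17 naive genes Stat3 rose (1.05 ± 0.16), Dppa3 fell (-2.12 ± 0.27) and 15 were not called. When adjusted over the list alone 6 rose and 2 fell, and the list passed camera upward (adjusted p = 0.004, but adjusted p = 0.621 with an estimated correlation). This call too rests on 1 library, since without replicate 2 of the f/f bodies the list mean went from 0.89 to 0.24 (adjusted p = 0.249). Klf4 was not called over all genes (2.65 ± 0.56, adjusted p = 0.0554), nor was Jam2 (2.74 ± 0.66, adjusted p = 0.077). Of 12 germline genes 3 rose (8 over the list alone), Sohlh2, Dnd1 (1.23 ± 0.21) and Tdrd1 (1.05 ± 0.21; camera, adjusted p = 1.2e-05, but adjusted p = 0.413 with an estimated correlation). Hox genes again gave Hoxb13 (1.77 ± 0.26) as 1 increase of 7, with 6 over the list alone (camera, adjusted p = 0.00069, but adjusted p = 0.413 with an estimated correlation).

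Pou5f1 fell by 0.76 on the log2 scale in DKO bodies (SE 0.14; limma, adjusted p = 0.0427), and the core pluripotency list gave 1 increase (Tex19.1) and 3 decreases (Lin28a, -2.76 ± 0.55; L1td1, -1.29 ± 0.20; Pou5f1) of 15 and did not pass camera. Of 15 imprinted genes 4 fell (Rian; Meg3, -3.39 ± 0.31; Mirg, -3.34 ± 0.39; Peg3, -2.09 ± 0.32) and 1 rose, with 5 and 1 over the list alone. The neural genes went both ways: of 8, Nes fell (-3.40 ± 0.47) and Sox1 rose (2.10 ± 0.37). The neural list mean of 0.07 depends on 1 library, since it was 0.61 without replicate 1 of the DKO bodies. Wnt targets gave 2 decreases of 10 (Sp5, and Axin2 at -1.78 ± 0.20, with 4 over the list alone). Fibroblast genes gave 2 of 20 (Tagln, and Thy1 at -1.02 ± 0.16, with 4 over the list alone). The fibroblast list did not pass in the main fit (mean -0.61; camera, adjusted p = 0.0767). It passed downward with median-of-ratios scaling, quantile scaling and edgeR (camera, adjusted p = 0.0458, 0.0127 and 0.0409). Without replicate 1 of the DKO bodies its mean was -1.20. Mesenchymal transition genes gave 3 decreases (Sparc, Snai1, Tgfb1) and 1 increase (Zeb1, 1.39 ± 0.27) of 13. Interferon genes gave 1 increase (Stat2, 0.84) and 2 decreases (Isg15, -1.39; Ddx58, -1.26) of 7 (2 up and 4 down over the list alone). Single changes were in BMP targets (Msx1 down, of 10; 2 down over the list alone), p53 genes (Perp, -1.40, of 16), hypoxia genes (Ndrg1, -1.08, of 16), cell cycle genes (Rrm2, 0.55, of 20) and housekeeping genes (Actb, -1.07 ± 0.19, of 11). No gene was called among 16 KMT2 complex, 5 blood and endothelial, 6 adipogenic and 20 ribosomal genes. Adjusted over the list alone, hypoxia genes gave 2 up and 4 down, housekeeping genes 1 up and 3 down, and blood and endothelial genes 1 up; lists whose second count is not given had the same one.

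**Figure D2:**
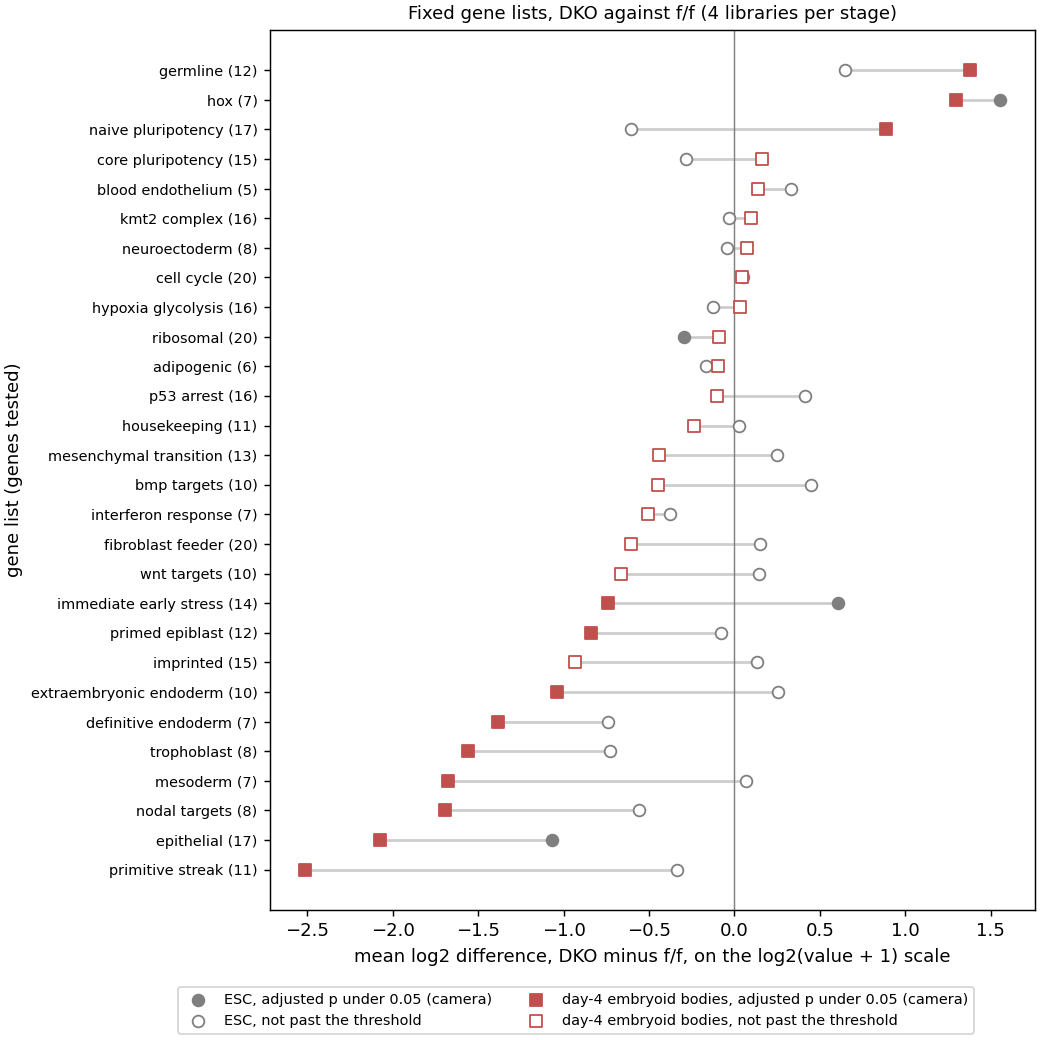
Mean log2 difference (DKO minus f/f) of 28 gene lists in ESC (grey circles) and day-4 bodies (red squares), n = 2 libraries per group; filled symbols passed camera with the preset correlation. The primitive streak list lies at -2.51 and the epithelial list at -2.08 in bodies, and the germline list at 1.38.

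In bodies 553 of 12466 genes passed (limma with Benjamini-Hochberg adjustment), 103 up and 450 down, of which 69 and 332 changed at least 2-fold, with a correlation of 0.708 across genes between the batches. Of the 28 lists 12 passed camera, 9 passed fry, and none passed camera with an estimated correlation (adjusted p = 0.290 for the smallest). The naive, primed, Hox, germline and immediate early lists passed camera and not fry (fry, adjusted p = 0.430, 0.229, 0.123, 0.0928 and 0.0928). Interferon genes and Wnt targets passed fry (adjusted p = 0.0164 and 0.0339) and not camera. In every other setting run for the 12 lists that passed camera, 8 also passed, and 4 did not in at least 1. The count of genes was 7 without replicate 1 of the f/f bodies, 107 without replicate 1 of the DKO bodies, 0 without replicate 2 of the f/f bodies and 799 without replicate 2 of the DKO bodies. It was 293 and 305 without replicate 1 and without replicate 2 of f/f ESC, and 327 among genes with a mean of at least 5. Between ESC and bodies, which share no library but may share a DKO clone, 108 genes fell in both comparisons, where independent lists would share 12.0, and 29 rose in both against 1.62. 7 genes rose in ESC and fell in bodies (7.08 for independent lists), and 0 fell in ESC and rose in bodies (2.75).

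The comparison of f/f bodies with f/f ESC gives the course of differentiation when MLL4 is present. Tbxt rose 17.2-fold (log2 change 4.11 ± 0.57, SE, n = 2; limma, adjusted p = 0.0166), and Klf4, a naive-state transcription factor, fell 13.2-fold, from 88.6 and 88.8 to 11.8 and 2.60 (-3.72 ± 0.56; adjusted p = 0.0181). Other large increases were in Car4 (3.43 ± 0.65), Krt18 (3.26 ± 0.58), Vrtn (3.21 ± 0.71), Sp5 (3.15 ± 0.42), Mixl1 (3.09 ± 0.25) and Fgf8 (3.07 ± 0.63), then in Krt8 (3.04 ± 0.64), Sall2 (2.97 ± 0.64) and the streak and endoderm regulator Eomes (2.94 ± 0.27). Other large decreases were in Klf2 (-3.41 ± 0.52), Nr0b1 (-3.40 ± 0.69), Krt42 (-3.36 ± 0.42), Fosb (-3.35 ± 0.38), Tcl1 (-3.25 ± 0.51), the nuclear receptor Esrrb (-3.18 ± 0.55), Septin1 (-3.18 ± 0.62), Zfp42 (Rex1, -2.91 ± 0.59) and Fos (-2.90 ± 0.40).

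Naive genes fell in f/f cells, 11 of 17 over all genes and 17 of 17 when adjusted over the list alone (camera, adjusted p = 1.1e-11), and of 15 core genes 2 fell, Zfp42 and Gdf3 (9 over the list alone; camera, adjusted p = 5e-05). Neither these 2 lists nor the 7 below passed with an estimated correlation (adjusted p = 0.622 for each) or with fry. Primed genes rose, 7 of 12 (10 over the list alone; camera, adjusted p = 8.1e-05, but adjusted p = 0.622 with an estimated correlation), with Sall2, Sox3 (2.57 ± 0.28), Pou3f1 (1.93 ± 0.46) and Zic2 (1.69 ± 0.15). Primitive streak genes rose, 8 of 11 (9 over the list alone; camera, adjusted p = 2.1e-05), as did 3 of 7 mesoderm genes (3 over the list alone; among them Msx1, 2.03, and Msx2, 1.96; camera, adjusted p = 0.042) and 7 of 17 epithelial genes (8 over the list alone; camera, adjusted p = 0.0079). With an estimated correlation each of these 3 lists had an adjusted p = 0.622. The mesoderm call was lost with a pseudocount of 5 (mean 0.73, adjusted p = 0.0786) and without replicate 2 of f/f ESC (adjusted p = 0.0523) or of the f/f bodies (mean 0.77 instead of 1.36, adjusted p = 0.0780). Of 14 immediate early genes 6 fell (8 over the list alone; camera, adjusted p = 6.6e-05), including Egr1 (-1.75 ± 0.42) and Dusp1 (-1.20 ± 0.28), and germline genes gave 1 decrease of 12 (1 over the list alone; camera, adjusted p = 0.023). Both had an adjusted p = 0.622 with an estimated correlation, and the germline call was lost with a pseudocount of 5 (adjusted p = 0.0603) and without replicate 2 of f/f ESC (adjusted p = 0.0529). Fibroblast genes gave 2 decreases of 20, S100a4 (-2.10 ± 0.27) and Col3a1 (-1.65 ± 0.41), with 3 down and 1 up over the list alone (camera, adjusted p = 0.00023, but adjusted p = 0.622 with an estimated correlation); ESC, unlike bodies, were kept on fibroblast feeders. Definitive endoderm genes gave 3 increases (Foxa2 at 1.85 ± 0.24, Gata4 at 1.65 and Gata6 at 1.41) and 1 decrease of 7 (4 and 1 over the list alone). That list did not pass camera in the main fit (mean 0.59). With edgeR its mean was 1.51 and it passed (camera, adjusted p = 0.0401).

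In f/f cells 1495 of 12466 genes passed (limma with Benjamini-Hochberg adjustment), and the share of increases moved with the scaling. As deposited 1014 rose and 481 fell, against 813 and 724 after median-of-ratios scaling and 658 and 556 after quantile scaling. With edgeR, which differs in model and input as well as scaling, 848 rose and 830 fell. The count was 3 without replicate 1 of f/f ESC, 3 without replicate 1 of the f/f bodies and 0 without replicate 2 of either. Without replicate 1 or replicate 2 of DKO ESC it was 925 or 985, and it was 990 among genes with a mean of at least 5.

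The matching comparison in DKO cells asks which part of that course takes place without MLL4. Zic2, a zinc finger gene of the primed epiblast, rose by 1.55 ± 0.15 on the log2 scale (SE, n = 2; limma, adjusted p = 0.0285), while the growth-response transcription factor Fos fell 29.1-fold, from 148 and 283 to 5.39 and 6.78 (-4.86 ± 0.40; adjusted p = 0.0173). The further decreases were Fosb (-4.99 ± 0.38), Egr2 (-3.69 ± 0.27), Atf3 (-3.64 ± 0.18), Egr1 (-3.27 ± 0.42), Ccn2 (-3.03 ± 0.24), Dusp1 (-2.94 ± 0.28), Nr4a1 (-2.88 ± 0.41), the macrophage lysozyme Lyz2 (-2.81 ± 0.33) and Ptgs2 (-2.77 ± 0.23). The further increases were Gdpd3 (4.46-fold), Sez6 (1.86 ± 0.21), Zic5 (1.35 ± 0.15), Prrt2 (1.33 ± 0.15), Scg5 (1.33 ± 0.17), the Wnt repressor Tcf7l1 (1.25 ± 0.17), Serinc5 (1.24 ± 0.16), Nrep (1.20 ± 0.16) and Sox4 (1.13 ± 0.17).

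None of 11 primitive streak genes was called over all genes in DKO cells and 1 fell over the list alone (Nodal, -1.49 ± 0.25), and the list mean was -0.01 (camera, adjusted p = 0.634). Of 17 naive genes Klf5 fell (-2.16 ± 0.31; 5 over the list alone; camera, adjusted p = 3.3e-05, but adjusted p = 0.486 with an estimated correlation), with Klf4 at -2.05 ± 0.56 (adjusted p = 0.135). Of 12 primed genes Zic2 and Zic5 rose (5 up and 1 down over the list alone; camera, adjusted p = 0.017, but adjusted p = 0.531 with an estimated correlation). The primed mean of 0.91 was 0.21 without replicate 2 of the DKO bodies (adjusted p = 0.647) and 0.57 without replicate 2 of DKO ESC (adjusted p = 0.133). Of 15 core genes Tdgf1 fell (-1.61 ± 0.23; 2 over the list alone; camera, adjusted p = 0.0013, but adjusted p = 0.486 with an estimated correlation). Immediate early genes gave 8 decreases of 14 (13 over the list alone; camera, adjusted p = 1.8e-16, but adjusted p = 0.486 with an estimated correlation). Fibroblast genes gave 2 decreases of 20, S100a4 (-2.77 ± 0.27) and Thy1 (-1.31 ± 0.16), and 15 over the list alone (camera, adjusted p = 1.2e-11, but adjusted p = 0.486 with an estimated correlation). Sox7 fell as 1 of 10 extraembryonic endoderm genes (-1.59 ± 0.23; 3 over the list alone; camera, adjusted p = 0.00017, but adjusted p = 0.486 with an estimated correlation). The p53 (5 down over the list alone), mesenchymal transition (2), imprinted (5 down and 1 up), BMP (2), Nodal (4) and Hox (0) lists passed camera downward with no member called over all genes. None of the 12 lists passed with an estimated correlation (adjusted p = 0.486 for the smallest). Of these 6, all but the p53 list were lost in at least 1 other setting. Without replicate 1 of the DKO bodies the BMP mean went from -0.45 to -0.11 (adjusted p = 0.659), the Nodal mean from -0.74 to -0.42 (adjusted p = 0.325) and the imprinted mean from -0.47 to -0.34 (adjusted p = 0.199). Without replicate 1 of DKO ESC the imprinted mean was -0.23 (adjusted p = 0.260) and the BMP mean -0.18 (adjusted p = 0.356). Without replicate 2 of the DKO bodies the mesenchymal mean went from -0.49 to -0.23 (adjusted p = 0.309) and the Hox mean from -0.44 to 0.18. The mesenchymal list was also lost without fibroblast genes (mean -0.26; camera, adjusted p = 0.251). That fit dropped list members at least 8-fold higher in fibroblasts than in replicate 2 of the f/f bodies, a library of the fit. It cannot tell whether fibroblast transcripts in the ESC libraries contribute to that call. Of the 12 lists the immediate early list alone passed fry (adjusted p = 0.0188). Of 5 blood and endothelial genes (2 down over the list alone) and 7 interferon genes (3 up and 1 down over the list alone) none was called over all genes; these lists passed fry (adjusted p = 0.0274 for each) and not camera.

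In DKO cells 103 of 12466 genes passed (limma with Benjamini-Hochberg adjustment), 25 up and 78 down, with a correlation of 0.382 across genes between the batches. The count was 3, 0, 4 and 0 without replicate 1 of f/f ESC, replicate 1 of DKO ESC, replicate 1 of the f/f bodies and replicate 2 of the DKO bodies. It was 15, 5 and 11 without replicate 2 of f/f ESC, replicate 2 of DKO ESC and replicate 2 of the f/f bodies. Of genes that rose in f/f cells 14 also rose in DKO cells (2.03 for independent lists), and of genes that fell 41 also fell (3.01). The lower count in DKO cells does not by itself show that the genotypes differ.

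The interaction, which tests that difference, gave 0 genes past the threshold in limma, with 1704 genes at an unadjusted p under 0.05. Its per-gene values correlated at 0.566 between the batches, across genes that are not independent replicates. The count of 0 does not show that the genotype effect is the same at both stages. edgeR gave 0, DESeq2 gave 435, and limma with a block for each batch within each stage gave 353. The smallest adjusted p in limma was 0.0657, that of Atf3 (-3.04 ± 0.25) among others. Gprc5c (-3.75 ± 0.39), Sox3 (-3.68 ± 0.39) and Mixl1 (-3.16 ± 0.35) were among the genes with an adjusted p of 0.0709. Tbxt differed by -3.90 ± 0.81 (adjusted p = 0.145) and Eomes by -2.92 ± 0.39 (adjusted p = 0.0865).

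Genes induced in f/f cells were also followed across batches, so that the library that chose a gene did not measure it. The 546 genes at least 2-fold induced in batch 1 had, in batch 2, a median rise of 1.29 in f/f and 0.50 in DKO cells on the log2 scale, and 78.8% of them were lower in DKO than in f/f bodies. The 759 genes chosen in batch 2 had, in batch 1, a median rise of 0.97 in f/f and 0.07 in DKO cells, and 88.1% of them were lower in DKO bodies. The median difference between DKO and f/f bodies was -0.53 and -0.74 (mean -0.63 ± 0.15, SD, n = 2 batches), each below all 10000 matched random lists, while the same genes differed by 0.07 and 0.06 in ESC. For 269 and 712 repressed genes the difference in bodies was 0.08 and 0.26 (mean 0.17 ± 0.13, SD, n = 2 batches), above all random lists, with 45.0% and 36.0% of genes lower in DKO. The repressed genes differed the other way in ESC, by -0.27 and -0.07. Both sets were chosen in f/f cells alone, and the random lists were matched on mean level and not on induction. Lines that respond in lasting but different ways, with neither response weaker, could show such induced genes lower and repressed genes higher in DKO bodies. A difference between the lines of equal size in ESC and bodies would not. Genes chosen in DKO cells were not followed, so the places among random lists cannot by themselves show a weaker response.

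The comparison of fibroblasts asks how the genotypes differ before factor delivery. With 1 library per genotype and stage, none of the values that follow for fibroblasts and day 20 has a replicate check, and none was tested. The integrin gene Itga7 stood at 6.06 FPKM in f/f fibroblasts and 145 FPKM in the library labelled DKO, and the growth factor gene Igf2 at 34.9 and 609 FPKM. Genes lower in the library labelled DKO included the ubiquitin-like interferon gene Isg15 (79.2 and 2.39 FPKM) and the water channel Aqp1 (100.1 and 3.80). So were the matrix genes Lum (52.7 and 2.00), Ltbp2 (50.8 and 1.58), Thbs2 (71.7 and 3.53), Npnt (53.3 and 2.61) and Smoc2 (45.1 and 2.09), and the integrin Itga3 (28.1 and 0.673). Higher were Nr4a3 (1.23 and 38.1), Shox2 (3.21 and 48.1), Stc2 (0.810 and 18.0), Il6 (1.94 and 19.5), Atf3 (4.93 and 39.4) and Hey1 (0.925 and 11.9). By the size rule 43 genes were higher and 155 lower.

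Interferon genes were lower in the fibroblast library labelled DKO for 15 of 15 measured, 12 of them at least 2-fold, such as Ifit3 (29.7 and 1.41 FPKM), with a median log2 difference of -1.84 (percentile 0 among matched random lists). Hox genes were lower for 22 of 25 (median -0.50, percentile 0). Imprinted genes were lower for 11 of 16 (median -0.70, percentile 0), such as Peg3 (65.6 and 5.81), Nnat (36.5 and 3.07) and Cdkn1c (13.7 and 0.619), with Igf2 the other way. Fibroblast genes were lower for 14 of 21 (median -0.25, percentile 0.24), among them Fbln2 (368 and 39.2), and BMP targets for 8 of 9 (median -0.51, percentile 0.61). Neuroectoderm (median 0.67, percentile 99.9) and extraembryonic endoderm genes (0.62, percentile 99.7) lay high, the latter only among members with a mean of at least 1 FPKM, since its median was 0.0098 with no minimum. The KMT2 complex (0.18, percentile 85.5) and cell cycle lists (0.06, percentile 39.7) lay within the random lists.

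At day 20 the comparison asks what the delivered factors brought about in each genotype. Pou5f1 stood at 19.8 FPKM in the f/f library and 0.118 FPKM in the library labelled DKO, Sox2 at 9.36 and 0.243, and the ESC gene L1td1 at 4.19 and 0.0145. Nanog, whose near-identical processed copies make its value uncertain, stood at 5.49 and 9.68 FPKM, and at 7.26 FPKM in f/f fibroblasts. Higher in the library labelled DKO were the glutamate receptor gene Gria4 (0.175 and 55.2), Itga7 (7.06 and 300.5), Ankrd1 (2.56 and 123), and Chac1 (1.43 and 55.5). So was Ndrg1 (17.5 and 240.1). Lower were the imprinted noncoding gene H19 (1712 and 11.3), Ly6a (252 and 0.980), Igfbp2 (1532 and 11.8), and Msln (174 and 0.626). They included Aldh3a1 (267 and 1.66), Thbs2 (539 and 4.39), Slurp1 (169 and 0.976), Crabp1 (186 and 1.28), Ccn5 (125 and 0.553) and Igfbp5 (129 and 0.773). By the size rule 147 genes were higher and 381 lower. Of these, 80 were lower in fibroblasts as well, where independent lists would share 5.90, and 14 were higher in both (0.632).

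The day-20 library labelled DKO was low in epithelial genes (6 of 7 measured out of 17 listed, median -2.09, percentile 0). Among them were Krt8 (32.0 and 0.118 FPKM), Cldn4 (3.95 and 0.0471) and Dsp (3.81 and 0.0312). Members near 0 in that library could be measured only through the f/f library, so the count partly follows from the filter. Core pluripotency genes were lower for 3 of the 5 with a mean of at least 1 FPKM (median -2.35, percentile 0). The 3 were L1td1 and the genes taken as delivered factors, Pou5f1 and Sox2. The core median was -0.17 with no minimum and -4.78 with a pseudocount of 0.1, and the epithelial median was -4.90 with that pseudocount. Fibroblast genes were lower for 16 of 21 (median -0.87, percentile 0), such as Lum (168 and 1.75) and Thy1 (119.7 and 1.08). Mesoderm genes (-0.87, percentile 0.18), imprinted genes (-0.51, percentile 0.11) and BMP targets (-0.76, percentile 0.85) also lay low. The interferon (median -0.23, percentile 25.8) and Hox lists (0.16, percentile 86.9), low in the fibroblast library labelled DKO, lay within the random lists at day 20. Cell cycle genes were higher for 15 of 20 (median 0.57, percentile 99.9) and immediate early genes for 10 of 14 (0.98, percentile 99.99), with Ccn1 at 122 and 1139 FPKM and Egr1 at 73.3 and 388.

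**Figure D3:**
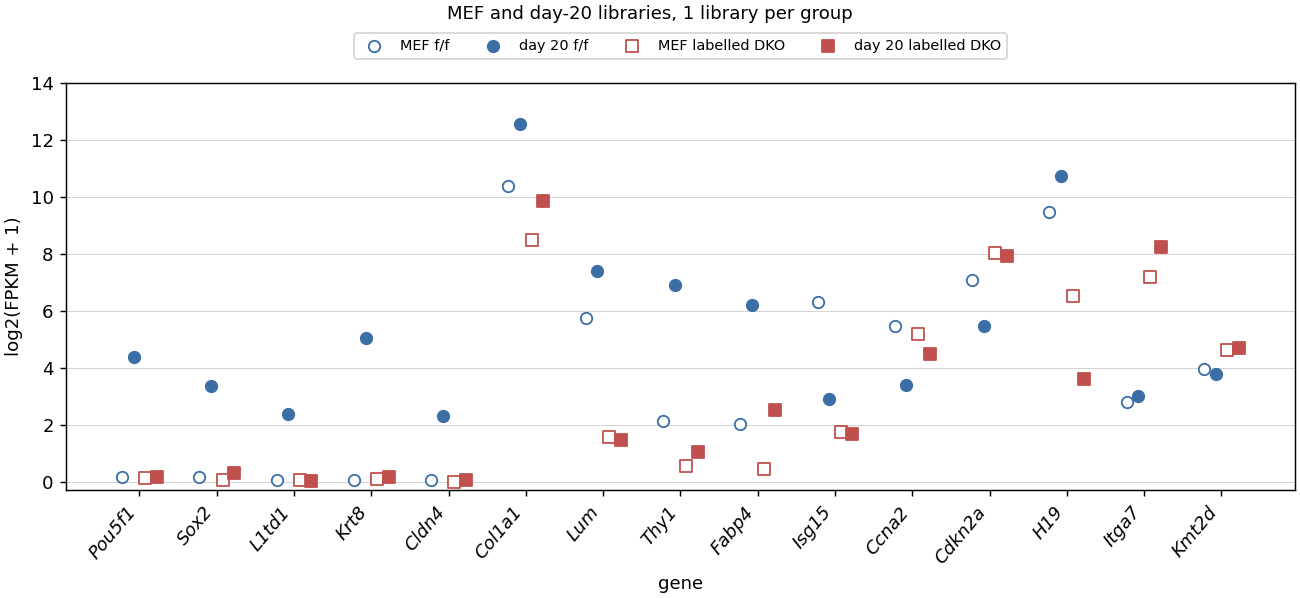
Levels of 15 genes as log2(FPKM + 1) in fibroblast and day-20 libraries labelled f/f or DKO, 1 library each. Pou5f1 stands at 19.8 FPKM in the f/f day-20 library and 0.118 FPKM in the library labelled DKO, and Kmt2d at 12.9 and 24.8 FPKM.

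Compared with f/f fibroblasts, the f/f day-20 library was higher in 202 genes and lower in 97. Higher were the aldehyde dehydrogenase Aldh3a1 (1.12 and 267 FPKM), Slurp1 (0.395 and 169), Msln (1.93 and 174), Nccrp1 (0.429 and 87.0), the keratin Krt14 (0.167 and 55.9) and the protease Mmp3 (0.192 and 47.4). Lower were the chemokine Ccl5 (44.7 and 0.452) and Ifit1 (36.6 and 1.61), as well as Il1rn (179.8 and 12.5), Ankrd1 (42.2 and 2.56) and Col2a1 (20.4 and 0.833). Epithelial genes were higher for 6 of 6 measured out of 17 listed (median 2.01, percentile 100) and core pluripotency genes for 3 of 5 (2.31, percentile 100). The 3 were L1td1 and the genes taken as delivered factors, Pou5f1 and Sox2. Epithelial or core members near 0 in fibroblasts could be measured only through the day-20 library, so both counts partly follow from the filter. Fibroblast genes were higher for 17 of 21 (1.23, percentile 100) and hypoxia genes for 15 of 15 (0.88, percentile 99.99). With no minimum the core median was 0.17, and with a pseudocount of 0.1 it was 4.87 and the epithelial median 4.29. Thy1 went from 3.37 to 119.7 FPKM and the adipocyte gene Fabp4 from 3.13 to 73.0, but Acta2 from 1544 to 174. Cell cycle genes were lower for 20 of 20 (median -1.56, percentile 0), with Ccna2 at 43.0 and 9.56 FPKM, and interferon genes for 15 of 15 (-1.96, percentile 0), while the arrest gene Cdkn1a went from 15.2 to 109.

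In cells labelled DKO, day 20 differed from fibroblasts by 54 higher and 37 lower genes. Higher were Gria4 (1.97 and 55.2 FPKM), Sparcl1 (0.126 and 17.2), the preadipocyte gene Dlk1 (2.38 and 50.9), Casp4 (2.54 and 49.4), Col3a1 (516 and 4606) and Dcn (2.70 and 27.5). Lower were Cbr2 (28.8 and 0.251), Aspn (69.2 and 2.36), Egfl6 (79.1 and 4.41), H19 (92.0 and 11.3), Col12a1 (569 and 78.3), Ogn (104 and 14.4) and Fhl1 (253 and 36.4). Cell cycle genes were lower for 19 of 20 (median -0.97, percentile 0), and hypoxia (0.99, percentile 100), adipogenic (percentile 99.99) and immediate early genes (0.60, percentile 99.97) lay high. The lists of genes higher in both genotypes shared 8 genes (1.09 if independent), and those lower shared 6 (0.359).

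To place the day-20 libraries between fibroblasts and ESC, 397 ESC-high genes had a median log2 level of 0.28 in f/f fibroblasts and 4.73 in f/f ESC (replicate 2). Their median was 0.88 in the f/f day-20 library, which is 0.134 of the way to ESC (95% bootstrap interval over genes 0.113 to 0.181). Of these genes 78 stood at least 2-fold above f/f fibroblasts and 4 at least 2-fold below. In the library labelled DKO the median was 0.22, a position of -0.0119 (-0.0267 to 0.00202), with 29 genes at least 2-fold above and 25 at least 2-fold below. For 281 fibroblast-high genes the median was 5.05 in fibroblasts and 1.15 in ESC, and 4.65 in the f/f and 4.28 in the DKO-labelled day-20 library, positions of 0.104 (0.0421 to 0.184) and 0.198 (0.145 to 0.259). On the same scale, set by f/f cells, the fibroblast library labelled DKO already lay at 0.124 (0.0814 to 0.187) for fibroblast-high genes and at -0.0257 (-0.0336 to -0.0102) for ESC-high genes, so part of the distance at day 20 may predate factor delivery. These levels compare libraries of the FPKM batch only, and the intervals cover the choice of genes and not the spread between cultures. The genes were chosen with the same libraries that set both ends of the scale. The choice alone can therefore move another fibroblast library off the fibroblast end. For fibroblast-high genes the f/f day-20 position of 0.104 was no farther than the 0.124 of untreated fibroblasts labelled DKO, so it does not by itself show a move toward ESC.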

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

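The tests that weigh explanations in this part were chosen only after the result was seen; the limma and camera tests of the interaction were planned, and its edgeR and DESeq2 tests were added after seeing the data.

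For 15 gene lists camera with a preset correlation called the interaction (adjusted over 28 lists). The interaction is the genotype effect in day-4 bodies minus that in ESC. With an estimated correlation no list passed (camera, smallest adjusted p = 0.315), and none passed fry (smallest adjusted p = 0.0858). The calls therefore rest on the preset correlation. The mean log2 difference of the effects was -2.18 for primitive streak genes, -1.74 for mesoderm, -1.29 for extraembryonic endoderm, -1.35 for immediate early genes, -1.13 for Nodal targets, -1.06 for imprinted genes, -1.01 for epithelial genes and -0.89 for BMP targets. It was -0.80 for Wnt targets, -0.76 for fibroblast genes, -0.69 for mesenchymal transition genes and -0.52 for p53 genes. It was above 0 for naive genes (1.49), germline genes (0.73) and ribosomal protein genes (0.21). Of the streak genes Tbxt, Mixl1 and Eomes carried the largest differences, at -3.90, -3.16 and -2.92. Over all genes limma called 0 (1704 at an unadjusted p under 0.05; edgeR 0, DESeq2 435), but adjusted over the list alone 9 of 11 streak genes passed, 7 each of 10 extraembryonic endoderm, 14 immediate early, 15 imprinted and 17 epithelial genes, and 4 of 10 Wnt targets. So did 3 of 8 Nodal targets, 3 of 17 naive genes, 2 each of the mesoderm, fibroblast, mesenchymal and BMP lists, 1 p53 gene and 0 germline and ribosomal genes. 7 of the 15 lists passed in every other setting run, and 8 were lost in at least 1. The fibroblast mean was -0.15 without replicate 1 of f/f ESC (adjusted p = 0.493), and the epithelial mean was -0.65 without replicate 1 of the DKO bodies (adjusted p = 0.0978). The p53 list was lost in 8 settings, with a mean of -0.25 without replicate 2 of the f/f bodies (adjusted p = 0.474) and -0.27 without replicate 1 of DKO ESC (adjusted p = 0.330). The BMP list was lost in 7, with a mean of -0.53 without replicate 2 of f/f ESC (adjusted p = 0.232) and -0.56 without replicate 1 of the DKO bodies (adjusted p = 0.283). The germline mean was 0.29 without replicate 1 of the DKO bodies (adjusted p = 0.0764) and 0.35 without replicate 1 of DKO ESC (adjusted p = 0.0666). Without replicate 2 of the DKO bodies the mesenchymal mean was -0.43 (adjusted p = 0.168) and the fibroblast mean -0.16 (adjusted p = 0.653), and without replicate 1 of them the Nodal mean was -0.81 (adjusted p = 0.0576). The epithelial mean was -0.58 without replicate 1 of DKO ESC (adjusted p = 0.253). The ribosomal mean was 0.11 after quantile scaling (adjusted p = 0.273) and 0.12 without replicate 2 of DKO ESC (adjusted p = 0.101).

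5 genes went opposite ways by size in comparisons with 1 library per group, and the difference was not tested. The collagen gene Col12a1 was higher in the fibroblast library labelled DKO by 2.52 on the log2 scale and the matrix gene Egfl6 by 2.55, the chemokine gene Ccl5 differed by -2.15, and each went the other way at day 20. From fibroblasts to day 20, Agtr2 differed by 2.87, Col12a1 by 2.43 and Ccn2 by -2.48 in f/f cells, and each went the other way in cells labelled DKO.

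ESC genes stood higher in the f/f day-20 library than in fibroblasts, with Pou5f1 at 3.04% and Sox2 at 4.19% of the ESC level. The 63 other genes abundant in ESC (at least 30 FPKM) and nearly silent in fibroblasts (under 0.5 FPKM) argue against transcripts of the delivered factors alone, since 12 of them (19%) stood at least 2-fold above fibroblasts, among them Gpc3, Fxyd6, Mdk, Spint2 and Cldn4. They also argue against fully ESC-like cells as the whole source of Pou5f1 and Sox2, since 46 of them (73.0%) lay under 1.52% of their ESC level, with a median of 0.336% (quartiles 0.171% and 1.71%). What stays open is the study's genotype, since in the library labelled DKO 1 such gene stood at least 2-fold above fibroblasts, but each genotype has 1 library at day 20, so genotype and culture cannot be told apart. Cells that turned on part of the ESC programme may be present in the f/f library, as a hypothesis that was not tested. Of the core pluripotency genes among the 63, L1td1 stood at 2.20% of its ESC level, Trim71 at 1.15% and Tdgf1 at 0.288%. Lin28a stood at 0.176%, Sall4 at 0.138%, Fgf4 at 0.136%, Utf1 at 0.0827%, Dppa4 at 0.0759% and Zfp42 at 0.0191%. The tests do not weigh delivered factors beside the rise of epithelial genes in that library.

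The DKO bodies of the batches differed in 18 genes that lay at least 4-fold below f/f in replicate 1 and less than 2-fold below it in replicate 2 (median 60.1% of the f/f level, of at least 5 FPKM), among them Dnmt3b (12.5% and 51.8% of the f/f level), Fgf5, Pim2, Lefty2, Trh and Sall2. Cells of the f/f genotype in the replicate 2 DKO library, which would need a share of 60.1%, are argued against, since 92 of 139 genes (66.2%) at least 4-fold lower in DKO bodies of replicate 1 and with at least 5 FPKM in f/f bodies of replicate 2 lay under 30.1% of their f/f level, and Tbxt lay at 2.33%. A wider response of the replicate 2 DKO culture to differentiation stays open. Over 359 genes induced in f/f cells of both batches, the DKO rise fell short of the f/f rise by less in replicate 2. The median gap was 0.30 on the log2 scale (bootstrap interval over genes 0.228 to 0.400, medians of -1.24 and -0.91), in the direction this explanation predicts. The interval covers the choice of genes and not the spread between cultures, with 1 library per group in each batch. The batches were counted differently, and the 359 genes may include genes of the pattern, so the gap does not decide the question. The name of the deposited table for the replicate 1 DKO bodies has a number after the genotype, which may be that of a clone, and the name for replicate 2 has none, so a difference between clones also stays open and was not tested.

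Fibroblast genes were lower in day-4 bodies than in ESC, with median changes of the 20 listed genes of -0.41 (13 lower) and -1.58 (17 lower) in f/f and -1.22 (18 lower) and -2.43 (19 lower) in DKO cells, in replicates 1 and 2. Library scaling is argued against, since the mean of the 4 medians was -1.41 as deposited and -1.44 after median-of-ratios scaling. Feeder cells in the ESC libraries could give such a change, because bodies were grown without feeders. That stays open at -0.41, where the interval in replicate 1 of f/f cells (-0.774 to 0.0147) includes 0, so feeder transcripts and loss of the ESC's own transcripts cannot be told apart.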

How the results depend on the processing

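edgeR, DESeq2, the mean over transcripts and the fits without small RNA or fibroblast genes were chosen after seeing the data. The counts for ESC (529), bodies (553), differentiation in f/f (1495) and in DKO (103) and the interaction (0) stayed within 1.5 times under median-of-ratios and quantile scaling, a pseudocount of 0.1, edgeR, the mean over transcripts and the fits without small RNA or fibroblast genes; edgeR shared 471 of the ESC and 425 of the body calls. The 52 calls of lists lay between 39 and 58 in every setting run for all contrasts.

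The counts that moved further follow by setting, and the cause was not tested unless given. With a pseudocount of 5 differentiation in DKO gave 67, and without a mean-variance trend 31. Without a filter, which adds low genes to the adjustment, ESC gave 207, bodies 289 and differentiation in DKO 1. With a mean of at least 5, which leaves fewer genes, bodies gave 327 and differentiation in f/f 990. DESeq2 gave 1506, 1431, 2741, 937 and 435 in the order above. A block for each batch within each stage gave 1428 in ESC, 1524 in bodies and 353 in the interaction; the stage contrasts cannot be fitted with it. Without the replicate block the counts were 0, 2, 0 and 1, because the batches were counted differently and their gap then enters the spread; 391 named genes kept their side of the threshold and 192 lost their call.

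Leaving out 1 library leaves its group with 1, which is then assumed to vary like the others. The range was 0 to 743 in ESC, 0 to 799 in bodies, 0 to 1886 for differentiation in f/f, 0 to 111 in DKO and 0 in the interaction. In DKO differentiation the Hox mean ranged from -1.05 to 0.18 and the epithelial mean from -0.38 to 0.47, so both changed direction with 1 library. The fibroblast mean in f/f differentiation turned to 0.37 without fibroblast genes, which removes its own members.

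Among genes taken by size, a 2-fold rule gave 790 in fibroblasts, 1877 at day 20, 1193 from fibroblasts to day 20 in f/f and 727 in cells labelled DKO, where a pseudocount of 0.1 gave 149. A pseudocount of 0.1 moved the position of ESC-high genes to 0.230 in the f/f and -0.0434 in the DKO-labelled day-20 library. Genes chosen at 4-fold moved the positions of the DKO-labelled library to 0.0529 (ESC-high, now above 0) and 0.107 (fibroblast-high), and the f/f fibroblast-high position to 0.0509. For induced genes the cross-batch difference was -0.48 with a pseudocount of 0.1 and -1.87 for genes chosen at 4-fold, in the same direction. For repressed genes (0.17) it was 0.27 with a pseudocount of 0.1, 0.12 at 4-fold and 0.11 without a filter. No named gene past the threshold changed direction in any setting. Depth limits low genes most in replicate 2 of the bodies, with 11366199 and 13463550 reads.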

Other observations

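The first-form values given in the last paragraph come from tests chosen only after the result was seen, and the genes named in the next 2 paragraphs were singled out after their values were seen.

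The other delivered factors were not highest in the f/f day-20 library, and a gene's value does not separate delivered from endogenous transcripts. Myc stood at 26.4 FPKM in the f/f and 105.5 FPKM in the DKO-labelled fibroblast library, and at 30.7 and 105.4 FPKM at day 20. Klf4 stood at 18.8 and 21.9 FPKM in fibroblasts and at 17.9 and 8.38 FPKM at day 20. Of the epithelial genes, Cdh1 stood at 0.188 FPKM in f/f fibroblasts and 3.24 FPKM in the f/f day-20 library and was listed at 0 in the day-20 library labelled DKO, and Epcam went from 0.0168 to 1.77 FPKM in f/f and was also listed at 0 in the library labelled DKO. Of the 63 genes other than the factors with at least 30 FPKM in ESC and under 0.5 FPKM in fibroblasts, those with the highest share of their ESC level in the f/f day-20 library were the cell surface gene Gpc3 (34.4%), Fxyd6 (11.3%), Mdk (9.72%) and Spint2 (5.70%), and in the library labelled DKO these stood at 0.168%, 0.0301%, 0.580% and 0.0754%.

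None of the 16 tested genes of the KMT2 complexes was called in ESC or in bodies. Ncoa6 differed by 0.73 ± 0.21 (SE, n = 2; limma, adjusted p = 0.115) and Kmt2b (MLL2) by -0.38 ± 0.13 (adjusted p = 0.15) in DKO ESC. Ash2l differed by 0.95 ± 0.21 in DKO bodies (adjusted p = 0.0609). At day 20 Pagr1a stood at 14.8 FPKM in f/f and 4.66 FPKM in the library labelled DKO, and Rbbp5 at 7.51 and 15.2 FPKM. In ESC the RNA-binding gene Lin28a stood at 144 FPKM in f/f and 20.7 FPKM in DKO cells of replicate 2, and at 190 and 49.5 FPKM in bodies. Over both replicates Lin28a was not called in ESC and was called lower in DKO bodies.

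Of 140 pairs of a list and a contrast, the mean, the median and the direction of camera differed in sign in 10, of which 0 passed the threshold. In ESC these were the naive list (mean -0.60, median 0.11), the neuroectoderm list (-0.04 and 0.14) and the housekeeping list (0.03 and 0.04, with camera downward). In bodies it was the adipogenic list (-0.10 and 0.02). For differentiation it was the trophoblast list in f/f (mean 0.65, camera downward), and in DKO the primitive streak list (-0.01 and 0.02) and the epithelial list (0.05 and 0.01, camera downward). In the interaction the cell cycle, interferon and adipogenic lists did so, with means of -0.01, -0.13 and 0.07.

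The tests of explanations replaced first forms whose values were already known. For the day-20 pattern, the first form asked whether Pou5f1 and Sox2 lay above the 95th percentile (5.57%) of the shares of the ESC-only genes, which they did not. For the bodies, it compared the DKO rise of 12 induced genes of the pattern between batches (0.17 in replicate 1 and 2.14 in replicate 2), which was void because the pattern had chosen the genes. For the fibroblast genes, it used 174 genes higher in fibroblasts than in replicate 2 of the f/f bodies, whose median change from ESC to bodies was 0.01 and -0.81 in f/f and -0.26 and -1.11 in DKO, in replicates 1 and 2. By its first rule the value of 0.01 counted against feeder cells, and that set was replaced by the list fixed in advance because it had been chosen with a library that enters the change.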
